A study of Mus musculus with 8 samples.

How the data were processed

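Gene expression was measured by RNA sequencing of sorted CD4+YFP+ cells from draining lymph nodes and spleen. Per the labels' protocols, sorting reached a purity above 97%, libraries were made from total RNA with a stranded total RNA kit and 15 cycles of PCR, and pooled libraries were run on HiSeq 2500 or MiSeq instruments; which library ran on which instrument is not given in the sources used here. The submitters' processing notes name FastQC, Trim Galore 0.4.2, cutadapt 1.12, STAR 2.5.1, Cuffnorm 2.2.1, Cuffdiff 2.2.1 and the mm10 build, while their settings, their order and the annotation are not given in the sources used here. The deposited table holds FPKM for 23997 genes, a unit taken from the name the authors gave the table and from its values; whether the libraries were also scaled to each other is not given in the sources used here. Of its 16 value columns, 8 matched the samples by name and 8 matched none and were not used. Gene symbols were looked up in the GENCODE M21 annotation of GRCm38, where 23604 matched.

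FPKM values are relative within a library, so a few abundant transcripts move all other values. Snora61 was at 31182.5 FPKM in sufficient replicate 4 and listed at 0 in the other independent libraries. Total FPKM ran from 474416 to 495435 in deficient and from 509592 to 613276 in sufficient libraries. Depth was estimated from the ratios of low values (up to 1 FPKM), which fall on shared steps where whole fragments were counted, and set to fragments with 680 genes of a single annotated transcript; it is an approximation, and in sufficient replicate 4 only 5.11% of the ratios fell on such steps, against 30.1% to 56.0% in the others. Whole reads were not recovered for all genes, so no count model was run. No interval from counting is given.

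Columns of the same group were compared before any gene was tested. For each pair the spread of log ratios over genes was divided by the spread that read sampling gives at the estimated depth, and pairs under 1.5 at 150 to 500 reads were averaged. This departs from the design written before the data were examined, which took all 8 columns as separate libraries, and the count under that design is given beside the main one. Simulated columns of 1 library gave at most 1.03 and those of separate libraries at least 12.8. The spread between the simulated libraries was set by choice. In the data, pairs of the same group that were not averaged lay between 2.57 and 5.55. The simulation is thus easier to separate than the data and does not test the bound of 1.5. The initial look at the table covered all of its columns.

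Genes with a mean of at least 1 FPKM over the 5 libraries were tested (10614 genes) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and the groups as the only term. Fold changes are deficient minus sufficient on the log2(FPKM + 1) scale, which understates the change of low genes. P-values are two-sided, and Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. On simulated data of 10499 genes with 2 and 3 libraries, 68% of 2-fold and 97% of 4-fold changes were recovered, 10 of 190 calls were false and 0 of 30 unchanged lists were called. The changed genes were drawn only from genes well above the filter, so the recovery does not hold for genes near 1 FPKM. Noise was simulated independently for each gene, so the unchanged lists held no correlation between genes. In the real lists the estimated correlation reached 0.908 (proliferation), so the simulation does not test list calls on them.

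The 33 gene lists were fixed before the data were examined: Treg core, suppressive mediators, effector Treg, resting and naive, Th1, Th2, Th17, Tfh and Tfr, NK and innate-like, TCR signalling, chemokine receptors and homing, IL-2 and STAT5, NF-kB and TNF receptors, interferon-stimulated, proliferation, apoptosis, Treg regulators, immediate-early, glycolysis, cholesterol synthesis, histone, ribosomal protein, mitochondrial and RNA quality genes, and markers of B, plasma, macrophage, neutrophil, dendritic, CD8 T, conventional CD4 T, erythroid and stromal cells. The 31 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists. With the preset correlation 14 lists were called, 7 in each direction, and with the estimated correlation 0 were. Fry called 5, namely the Treg core, NK, dendritic, IL-2 and Th17 lists. Th17 was not called by camera.

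Named genes followed a rule fixed beforehand: Bcl11b, the 12 largest increases and 12 largest decreases among called genes with no overlap between groups (predicted, small RNA and pseudogene names apart, up to 2 per direction), the up to 4 members of each list with the lowest adjusted p, and 10 Treg genes always named. Called list members outside it (Gpr83, Nrp1, Folr4, Rgs1, Klrk1, Spic, Hmox1 and Cd68), C1qa and Ms4a6c were named after their values were seen, and 1 called list member is not reported here. Members under the rule that did not pass are named only in part. Genes left to the last part of the rule were Gm5150 and 1700026L06Rik, with log2 fold changes of 1.72 and 1.71, and Snord15b and Ceacam-ps1, with -1.96 and -1.09.

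Alternatives covered the pseudocount, the filter, 3 scalings, the variance model, sample weights, a replicate block and leaving out each column. The 8 columns as separate libraries, the fit written in the design, became an alternative once columns had been averaged. Chosen after seeing the data were a correlation within libraries over the 8 columns, other ways of merging columns, short transcripts left out, each merged library left out, and a macrophage marker score as a covariate. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Single values were compared with exact two-sided permutation tests over 10 assignments, whose smallest p is 0.1.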

Results

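RNA sequencing measured gene expression in regulatory T (Treg) cells, the CD4 T cell lineage defined by the transcription factor Foxp3, from mice of the C57BL/6 strain. Per the labels, the cells were sorted as CD4+YFP+ from draining lymph nodes and spleen of animals with 1 Foxp3 allele that carries a YFP-Cre fusion. The deposited values covered 8 libraries in 2 groups of 4. Bcl11b-deficient cells carried 2 floxed copies of Bcl11b, a zinc finger transcription factor of the T cell lineage, and Bcl11b-sufficient cells carried 1 floxed and 1 wild-type copy. The comparison asked how gene expression in Treg cells differs when Bcl11b is deleted in them. Values were FPKM for 23997 genes. Relative depth, read from the steps between low FPKM values, ran from 0.936 to 4.13 times that of deficient replicate 1, which corresponds to approximately 2630000 to 11600000 fragments per library. Of the genes in the table, 37.4% to 47.0% were listed at 0 in a given library.

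The 8 libraries held 5 independent ones. Deficient replicates 1 and 3, deficient replicates 2 and 4, and sufficient replicates 1 and 3 differed within each pair by little more than the sampling noise of their reads, with a spread of 1.09 to 1.22 times that noise for genes at 150 to 500 reads. The 9 other pairs of the same group lay between 2.57 and 5.55 times and the 16 pairs of different groups between 3.70 and 9.67 times. Each near-identical pair was therefore averaged and counted as 1 sample, which left 2 deficient libraries and 3 sufficient libraries. Nothing in the labels states that the remaining libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

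**Figure D1:**
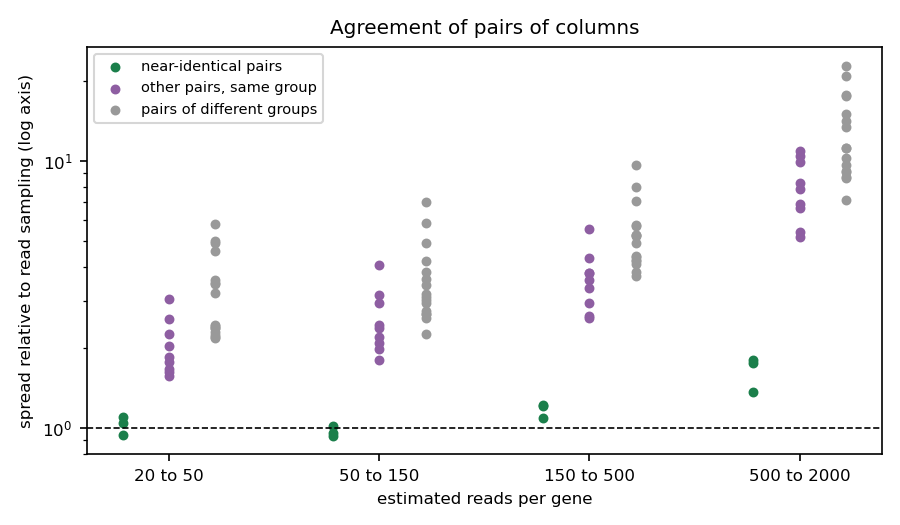
Spread of log ratios between 2 columns relative to that of read sampling (log axis) for genes grouped by estimated reads; each point is a pair of columns and the dashed line marks a spread equal to sampling noise. The 3 near-identical pairs lie between 1.09 and 1.22 at 150 to 500 reads, below the other 9 pairs of the same group at 2.57 or more.

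Bcl11b itself (ENSMUSG00000048251.15, chromosome 12, 107910403 to 108003602, minus strand in the GRCm38 annotation) was lower in every deficient library. It measured 24.2, 19.3, 24.6 and 18.7 FPKM in deficient replicates 1 to 4 and 42.4, 46.5, 42.4 and 39.1 FPKM in sufficient replicates 1 to 4. The means were 21.7 ± 3.83 FPKM (SD, n = 2) and 42.7 ± 3.68 FPKM (SD, n = 3), so deficient cells held 50.8% of the sufficient level. The log2 fold change was -0.95 (SE 0.14, limma adjusted p = 0.0238). The exact two-sided permutation test gave p = 0.1, the smallest that 10 assignments of 5 libraries allow. A value per gene does not show which exons were read, and the sufficient cells also carry 1 floxed copy. The adjusted p was 0.0602 without sufficient replicate 2, 0.0726 with no filter on low values and 0.0821 after scaling libraries to equal totals. The call also ended with any merged library left out, at a log2 fold change of -1.13 (adjusted p = 0.0774) without deficient replicates 1 and 3, -0.78 (0.133) without deficient replicates 2 and 4 and -0.95 (0.0522) without sufficient replicates 1 and 3. With a macrophage marker score as a covariate it ended too (-1.21, 0.842).

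Libraries of sorted Bcl11b-deficient cells had lower levels of Treg core genes and higher levels of NK and innate-like genes and of macrophage markers, as lists called by camera at a preset correlation. With an estimated correlation none of these 3 lists passed (adjusted p = 0.105, 0.293 and 0.293). Il10, an immunosuppressive cytokine, fell from 14.5 ± 5.29 to 1.47 ± 0.645 FPKM (SD, n = 3 and 2), and Ctla4, an inhibitory receptor, fell from 375 ± 102 to 111 ± 11.2 FPKM. Fcer1g, the signalling subunit shared by several Fc and NK receptors, rose from 4.77 ± 3.30 to 265 ± 25.4 FPKM, a log2 fold change of 5.77 (SE 0.56). Foxp3 was 153 ± 0.517 FPKM in deficient and 187 ± 18.8 FPKM in sufficient libraries, a log2 fold change of -0.28 (SE 0.12) that did not pass (adjusted p = 0.285). Markers of macrophages also rose in the same libraries, with Lyz2 at 110 ± 67.5 against 8.64 ± 5.93 FPKM.

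Among 10614 genes tested, 205 were higher and 74 lower in deficient libraries (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold on the log2(FPKM + 1) scale, 151 genes were higher and 31 lower. The count fell with any independent library left out. It was 80 without sufficient replicate 2, 133 without sufficient replicate 4 and 167 without sufficient replicates 1 and 3. It also fell without either deficient library, which leaves 1 deficient library. Leaving out a library removes a residual degree of freedom, which alone lowers the power. These falls therefore cannot show whether the count rests on particular libraries. With the 8 columns taken as separate libraries, as the design foresaw, the count was 1851. With totals made equal, which shifted the median of all genes to 0.18 on the log2 scale, 91.8% of 368 calls were higher, against 73.5% here.

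Treg signature genes fell as a group. Of 28 tested members of the Treg core list, 0 were higher and 9 lower over all genes, and adjusted over the list alone 0 were higher and 23 lower, with a median log2 fold change of -0.83 (camera adjusted p = 3.76e-18, adjusted p = 0.105 with an estimated correlation). Tnfrsf4, a costimulatory receptor of the TNF receptor family, fell from 190 ± 28.9 to 60.04 ± 0.622 FPKM (log2 fold change -1.64, SE 0.14, adjusted p = 0.00800). Lrrc32, which encodes the surface docking protein of latent TGF-beta, fell from 127 ± 28.1 to 35.4 ± 3.98 FPKM (log2 fold change -1.80, SE 0.20, adjusted p = 0.00982). Ctla4 had a log2 fold change of -1.72 (SE 0.22, adjusted p = 0.0174). Itgae, the integrin alpha chain that binds E-cadherin, fell from 19.5 ± 5.51 to 6.36 ± 2.75 FPKM. The other called members were Tnfrsf9, Gpr83, Nrp1, Folr4 and Rgs1. Il2ra, the high-affinity IL-2 receptor chain, measured 112 ± 13.5 against 179 ± 26.1 FPKM (adjusted p = 0.0783), Ikzf2 43.7 ± 3.36 against 65.6 ± 14.9 FPKM (adjusted p = 0.178), Tnfrsf18 200.0 ± 4.84 against 279 ± 19.5 FPKM (adjusted p = 0.0810) and Icos 43.0 ± 10.6 against 59.0 ± 9.43 FPKM (adjusted p = 0.276). Of the core members, 3 were called lower without sufficient replicate 2, 6 without sufficient replicate 4 and 0 without either deficient library. Macrophage marker levels in the same deficient libraries were high, with a median log2 fold change of 2.62 for that list.

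The lists of suppressive function and of effector Treg cells were also called lower, though only by camera at the preset correlation. In the list of suppressive mediators 1 of 20 tested members was higher and 3 lower, and adjusted over the list alone 1 was higher and 10 lower (median -0.57, camera adjusted p = 1.89e-05, adjusted p = 0.293 with an estimated correlation). Il10 had the most negative log2 fold change, -2.62 (SE 0.31, adjusted p = 0.0130), and the member that rose was Gzma, which encodes a cytotoxic granule protease. In the list of effector Treg genes 1 of 29 was higher and 3 lower, and adjusted over the list alone 1 was higher and 9 lower (median -0.43, camera adjusted p = 7.14e-05, adjusted p = 0.380 with an estimated correlation). Lgals3, a galectin also abundant in macrophages, was the member that rose, from 4.50 ± 0.288 to 17.0 ± 4.03 FPKM. In the list of NF-kB and TNF receptor family genes 0 of 23 were higher and 2 lower, and adjusted over the list alone 0 were higher and 3 lower (median -0.32, camera adjusted p = 7.14e-05, adjusted p = 0.364 with an estimated correlation). The genes called lower in these lists were largely Treg core members counted above. They were Lrrc32 and Ctla4 of the mediators, Tnfrsf9 and Itgae of the effector genes, and Tnfrsf4 and Tnfrsf9 of the NF-kB list. The only other was Il10, in both the mediator and effector lists. Other genes with large decreases were Gbp2b, the phosphatase genes Dusp5 and Dusp10, Bmyc, Tgif1, Gata1 and Hmgn3, with log2 fold changes from -1.89 for Gbp2b to -1.31 for Hmgn3.

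Genes of the NK and innate-like list rose. Of 17 tested members 7 were higher and 0 lower, and adjusted over the list alone 10 were higher and 1 lower (median log2 fold change 1.07, camera adjusted p = 3.49e-08, adjusted p = 0.293 with an estimated correlation). Beside Fcer1g these were Klrd1, an NK receptor subunit, at 15.8 ± 5.38 against 0.383 ± 0.366 FPKM (log2 fold change 3.60, SE 0.28, adjusted p = 0.00782), Cd160 at 32.1 ± 7.28 against 7.43 ± 0.360 FPKM, Gzma at 22.04 ± 13.4 against 1.33 ± 1.16 FPKM, Tyrobp, a signalling adaptor of NK and myeloid receptors, at 51.8 ± 18.6 against 5.73 ± 4.54 FPKM, Klrb1b and Klrk1. Fcer1g measured 253, 286, 241 and 280 FPKM in deficient replicates 1 to 4 and 0.679, 6.93, 1.28 and 6.41 FPKM in sufficient replicates 1 to 4. The adjusted p of Fcer1g was 0.0721 with robust empirical Bayes, 0.0510 without filter, 0.0774 without deficient replicates 1 and 3 and 0.0797 without deficient replicates 2 and 4. Of the list, 2 members were called higher without deficient replicates 1 and 3 and 1 without deficient replicates 2 and 4. Macrophage markers also rose in deficient libraries, but mostly differed from this list between the 2 deficient libraries. The ratio of the first over the second had a median of 0.724 in the 7 called NK-list genes and 1.79 in the macrophage list. Single genes departed from this, such as Tyrobp at 1.68 and Itgam at 0.551.

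Markers of macrophages and monocytes rose in the same libraries. Of 16 tested members 9 were higher and 0 lower, and adjusted over the list alone 15 were higher and 0 lower (median log2 fold change 2.62, camera adjusted p = 1.98e-15, adjusted p = 0.293 with an estimated correlation). C1qa, named after its values were seen, measured 96.7 and 38.9 FPKM in the 2 deficient libraries and 0.900, 11.2 and 11.1 FPKM in the 3 sufficient libraries. Fcgr3, an Fc receptor, measured 22.4 ± 0.570 against 1.35 ± 0.943 FPKM (log2 fold change 3.40, SE 0.32, adjusted p = 0.00836), and Emr1, Ly6c2, Itgam, Spic, Hmox1 and Cd68 were also called. Genes outside the list with large increases were Mpeg1, Fcna, Slc40a1, the iron exporter, Cd5l and Hes1, a transcription factor induced by Notch signalling, which rose from 0.799 ± 0.373 to 11.7 ± 4.58 FPKM. Of the marker genes, 4 were called higher without sufficient replicate 2, 3 without sufficient replicate 4 and 0 without either deficient library. With the mean of these markers as a covariate, chosen after seeing the data, limma called 0 genes of any kind (592 at an unadjusted p under 0.05); this score nearly followed the groups, at 4.88 and 4.26 in deficient and 1.44 to 2.58 in sufficient libraries. Under that covariate the Treg core list kept a median of -0.95 and its camera call at the preset correlation. Fcer1g had a log2 fold change of 2.57, against 5.77 in the main fit, and was not called.

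**Figure D2:**
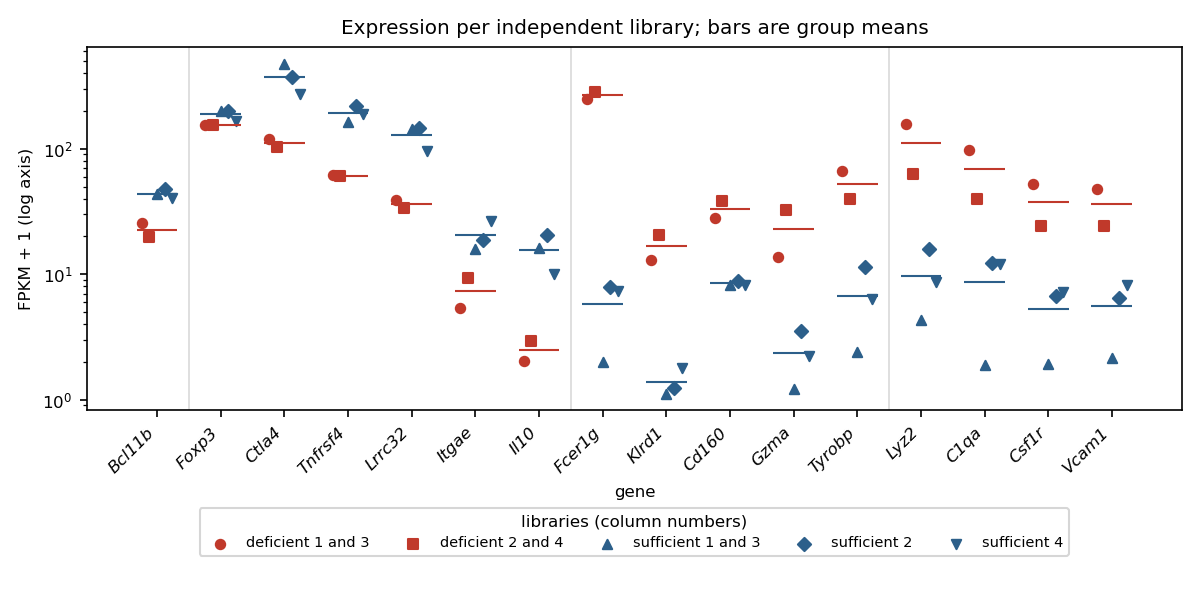
FPKM + 1 on a log axis in each of the 5 independent libraries for Bcl11b, Treg genes, NK and innate-like genes and macrophage genes; points are libraries and bars are group means. Fcer1g lies at 247 and 283 FPKM in the 2 deficient libraries and below 7 FPKM in the sufficient ones, and macrophage genes are lowest in the library of sufficient replicates 1 and 3.

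Lists of other cell types moved in the same direction. Dendritic cell markers had 3 of 9 members higher and 0 lower, and adjusted over the list alone 5 higher and 0 lower (median 0.74, camera adjusted p = 1.18e-05, adjusted p = 0.293 with an estimated correlation). B cell markers had 1 of 9 higher and 0 lower, and adjusted over the list alone 4 higher and 0 lower (median 1.06, camera adjusted p = 0.00409, adjusted p = 0.397 with an estimated correlation). Siglech rose from 0.146 ± 0.126 to 4.32 ± 2.79 FPKM. Klrb1f, placed in the dendritic list beforehand though it shares a family name with Klrb1b of the NK list, rose from 1.33 ± 0.366 to 5.85 ± 2.26 FPKM (log2 fold change 1.53, SE 0.25, limma adjusted p = 0.0319). In deficient replicates 1 to 4 Klrb1f measured 3.97, 8.07, 4.53 and 6.83 FPKM, and Siglech 6.68, 1.91, 5.91 and 2.78 FPKM. These members of the dendritic list therefore did not vary together. Batf3, a transcription factor of dendritic cells, rose from 0.499 ± 0.343 to 3.82 ± 1.62 FPKM (log2 fold change 1.66, SE 0.29, adjusted p = 0.0366). The B cell marker Ly6d rose from 3.61 ± 0.650 to 8.84 ± 0.550 FPKM. Klrb1f and Batf3 lost their calls with no filter (adjusted p = 0.102 for each), without sufficient replicate 2 or 4 and with any merged library left out. Batf3 also lost it with a pseudocount of 0.1, with quantile normalization and without deficient replicate 3. With the macrophage score as a covariate the dendritic call ended (median 0.14, camera adjusted p = 0.384). The B cell median turned (-1.39, camera adjusted p = 0.0161). Conventional CD4 T cell markers had 2 of 7 members higher and 0 lower, and adjusted over the list alone 3 higher and 0 lower (median 0.66, camera adjusted p = 0.00430, adjusted p = 0.293 with an estimated correlation), with Pde3b at 14.2 ± 1.49 against 3.69 ± 0.890 FPKM and Dapl1 at 60.3 ± 8.58 against 20.2 ± 4.61 FPKM.

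Interferon-stimulated genes shifted upward as a list, with 0 of 31 higher and 0 lower over all genes and, adjusted over the list alone, 13 higher and 1 lower (median 0.38, camera adjusted p = 4.25e-06, adjusted p = 0.364 with an estimated correlation). Ifit3 measured 55.7 ± 0.862 against 30.2 ± 6.42 FPKM (adjusted p = 0.0550). Genes of the IL-2 and STAT5 list had 1 of 23 higher, Pim2, a survival kinase at 42.9 ± 0.551 against 21.5 ± 1.89 FPKM, and 0 lower, and adjusted over the list alone 1 higher and 5 lower (median -0.20, camera adjusted p = 0.0117, adjusted p = 0.293 with an estimated correlation). Glycolysis genes had 1 of 18 higher, Tpi1, and 0 lower, and adjusted over the list alone 1 higher and 4 lower (median -0.20, camera adjusted p = 0.0101, adjusted p = 0.364 with an estimated correlation). Ribosomal protein genes had 0 of 37 higher and 0 lower by either adjustment over the list alone or over all genes (median -0.45, camera adjusted p = 3.51e-12, adjusted p = 0.397 with an estimated correlation). Quantile normalization ended the ribosomal call (median -0.06, camera adjusted p = 0.175), the IL-2 call (camera adjusted p = 0.145) and the glycolysis call (camera adjusted p = 0.0972), and the last also ended without deficient replicates 1 and 3 (camera adjusted p = 0.0522). The macrophage score as a covariate ended all 3 (camera adjusted p = 0.335 for the ribosomal, 0.726 for the IL-2 and 0.344 for the glycolysis list). With equal totals, which moved the median of all genes to 0.18, the IL-2 and glycolysis medians turned to 0.0138 and 0.00834. Both lists stayed called there (camera adjusted p = 0.00748 and 0.0258). The share of total FPKM in all 77 ribosomal protein genes of the table, more than the 37 of the list, was 22.7% ± 0.867 (SD, n = 2) against 26.8% ± 1.44 (SD, n = 3), with an exact permutation p = 0.1. Proliferation genes had 0 of 31 higher and 0 lower over all genes and adjusted over the list alone (median 0.24, camera adjusted p = 0.0404, adjusted p = 0.744 with an estimated correlation). The proliferation call ended with no filter (camera adjusted p = 0.173), equal totals (0.301), quantile normalization (0.0611), no trend (0.0507), array weights (0.203), the 8 columns as separate libraries (0.179), these with a correlation within libraries (0.179) or with the replicate block (0.153), and without deficient replicate 4 (0.0723), sufficient replicate 4 (0.628, median -0.07) or deficient replicates 2 and 4 (0.964, median -0.01).

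**Figure D3:**
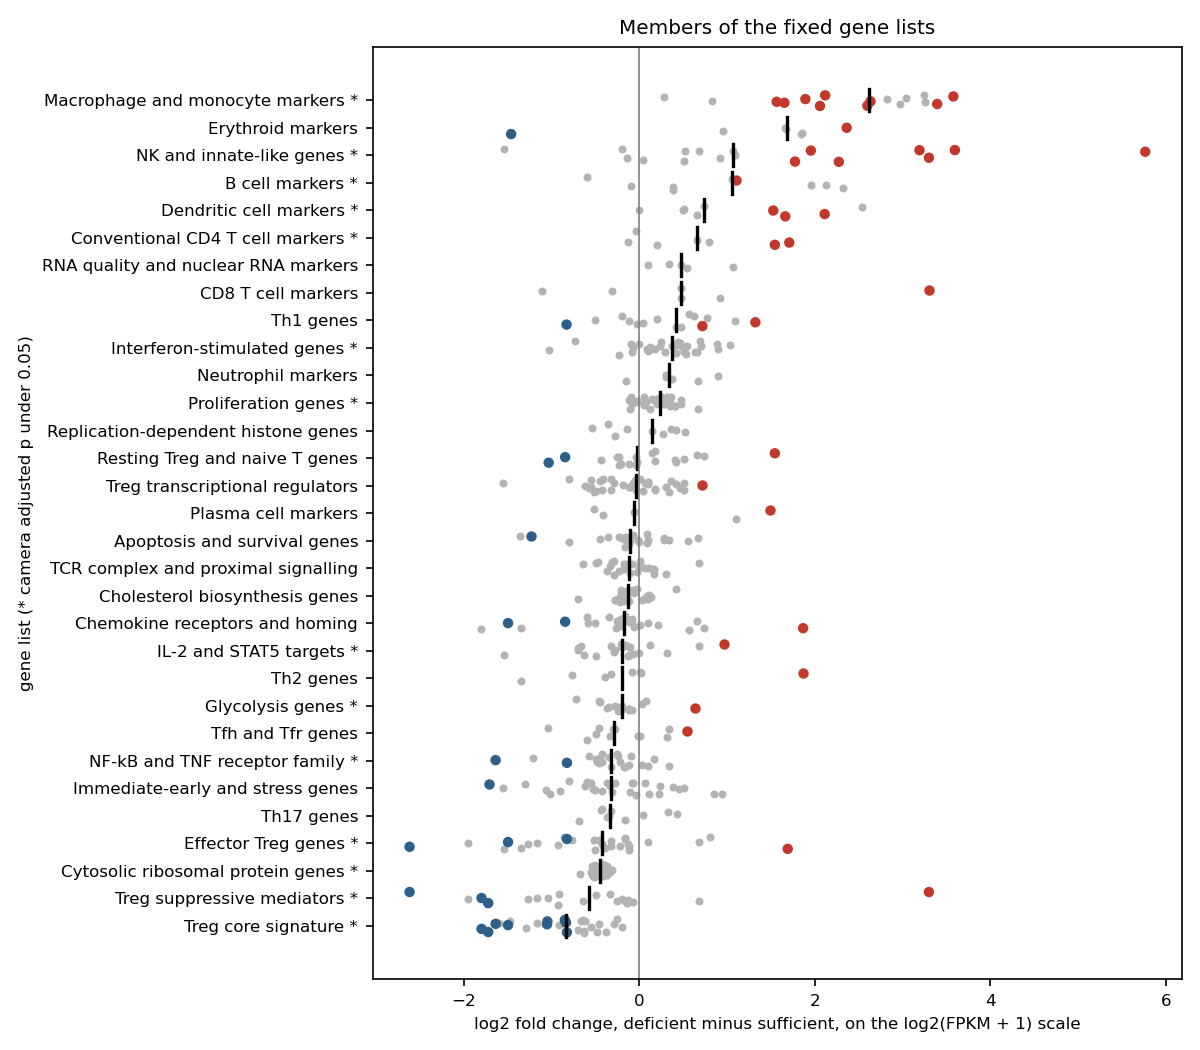
Log2 fold changes (deficient minus sufficient, on the log2(FPKM + 1) scale) of the tested members of 31 gene lists; coloured points passed the test over all genes, grey points did not, black bars are list medians and asterisks mark lists called by camera. The Treg core list has a median of -0.83 and the macrophage list of 2.62.

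The remaining lists were not called by camera, while fry called the Th17 list (fry adjusted p = 0.00703), of which 0 of 10 members were higher and 0 lower over all genes and, adjusted over the list alone, 0 higher and 1 lower. T helper genes gave single changes within uncalled lists, since Il12rb2 and Runx3 of the Th1 list rose and Ifngr1 fell, Ccr3 of the Th2 list rose and Slamf6 of the Tfh list rose. Of naive T cell genes Dapl1 rose while Ccr7, a lymph node homing receptor, fell from 262 ± 49.2 to 144 ± 0.228 FPKM and Ly6c1 fell from 131 ± 30.8 to 62.7 ± 2.31 FPKM. Tcf7 measured 455 ± 25.5 against 340 ± 13.4 FPKM (adjusted p = 0.123), Lef1 117 ± 7.90 against 103 ± 8.61 FPKM (adjusted p = 0.456) and Gata3 39.9 ± 5.04 against 50.3 ± 8.49 FPKM (adjusted p = 0.353). Of 24 tested TCR complex and signalling genes 0 were higher and 0 lower over all genes and adjusted over the list alone (median -0.12, camera adjusted p = 0.0863).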

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

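The alternatives chosen after seeing the data are those on merging, on a correlation within libraries, on whole libraries left out, on short transcripts and on the macrophage score. Of 279 changed genes (182 at least 2-fold), the count was 182 with a pseudocount of 0.1, 99 (56) with no filter, of which 54 were shared, and 113 (69) at a mean of at least 5 FPKM. The correlations of deviations between equal replicate numbers were 0.03, 0.06, 0.13 and 0.09, and between unequal numbers they ran from -0.108 to 0.13. Values this small, in part over near-identical columns, cannot decide whether replicate numbers pair the libraries. With the replicate block on 8 separate columns 1418 (311) genes were called. The 8 columns as separate libraries, the fit of the original design, gave 1851 (311) and with a correlation within libraries 690 (277). Leaving out single columns or whole merged libraries gave 8 to 297 genes (8 to 199 at least 2-fold), with 80 the lowest for a single column; whole merged libraries left out gave 16 (16), 8 (8) and 167, and where this leaves 1 deficient library it is assumed to vary like the other group. Apart from the macrophage score below, the other alternatives gave counts within 1.5 times.

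Bcl11b kept its direction throughout. Its log2 fold change was -0.95 (adjusted p = 0.0726) with no filter, -0.75 (0.0821) with equal totals, -0.89 (0.0602) without sufficient replicate 2, and -1.13 (0.0774), -0.78 (0.133) and -0.95 (0.0522) without deficient 1 and 3, deficient 2 and 4, and sufficient 1 and 3. Of 14 called lists, 0 held with an estimated correlation. Fry called 5 lists, of which Th17 was not among the 14. Quantile normalization ended 4 list calls (IL-2, proliferation, glycolysis, ribosomal). Lists not called in the main fit but called under at least 1 alternative were the chemokine receptor, cholesterol synthesis, erythroid, immediate-early, neutrophil, RNA quality, TCR, Th1 and Th17 lists. Of 52 called named genes, 42 lost the call with no filter, 30 without sufficient replicate 2, 28 without sufficient replicate 4, 44 without deficient 1 and 3, 49 without deficient 2 and 4, and under the macrophage score 46, with the other 6 turned. The proliferation list had a median of -0.0677 without sufficient replicate 4, -0.0123 without deficient 2 and 4, and 0.488 without deficient 1 and 3.

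With the macrophage score as a covariate 0 genes (0 at least 2-fold) were called by limma, 592 at an unadjusted p under 0.05, and 9 lists, with the IL-2, glycolysis, ribosomal, dendritic and macrophage calls lost; Bcl11b was at -1.21 (adjusted p = 0.842). The score was 4.88 and 4.26 in deficient and 1.44 to 2.58 in sufficient libraries, so it nearly follows the groups and leaves 2 residual degrees of freedom, which alone lowers the power. Medians turned for the B cell list (-1.39); the macrophage list had a median of 0.16 with a test in the other direction, which the score forces. Fold changes turned for Tyrobp (-0.41), Fcna (-0.0342), Slc40a1 (-0.24), Cd5l (-0.35), Gbp2b (0.0185) and Ccr3 (-0.14). Whether depth or anything else caused the changes under the alternatives was not tested.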

Other observations

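Other lists fixed beforehand held few changes. Erythroid markers had 1 of 7 members higher, Car2, and 1 lower, Gata1, by either adjustment over all genes or adjusted over the list alone (median 1.68, camera adjusted p = 0.116), and Hbb-b1, named after its values were seen, measured 9.64 and 116 FPKM in the 2 deficient libraries and 0.0806, 70.4 and 16.4 FPKM in the sufficient ones. CD8 T cell markers (median 0.47, camera adjusted p = 0.302) had 1 of 6 higher, Gzma, plasma cell markers (median -0.05, camera adjusted p = 0.987, direction up) 1 of 5, Mzb1, and neutrophil markers (median 0.34, camera adjusted p = 0.477) 0 of 6. Camera adjusted p-values were 0.0845 for Th1, 0.315 for Th2, 0.0985 for Th17, 0.544 for Tfh, 0.0970 for chemokine receptor, 0.231 for apoptosis, 0.502 for Treg regulator, 0.0863 for immediate-early, 0.151 for cholesterol synthesis, 0.856 for histone and 0.151 for RNA quality genes, and 0.696 for resting and naive genes, whose median of -0.03 and test direction differ. Of apoptosis genes Cdkn1a fell from 5.46 ± 1.45 to 1.71 ± 0.0479 FPKM. The stromal and mitochondrial lists had too few tested members.

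Among the tests in this part, those on the deposited columns, on the ratio of the 2 deficient libraries, on NK transcripts against Klrd1 (restated to cover all 7 transcripts), on the joint variation of macrophage markers and on the share of T cells were chosen after the result was seen. Of the 10 splits of the 5 libraries into 2 and 3, 1 gave as many genes as the genotype split, which is that split itself, with 279 genes against at most 2 in another; so few splits cannot give a share under 0.05.

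NK and myeloid genes both rose in deficient libraries, though the sort took CD4+YFP+ cells. Against NK cells as the source of Fcer1g, the median excess of Gzma, Ccl5, Nkg7, Klrb1c, Ncr1, Tyrobp and Prf1 was 2.12% of that of Fcer1g (0.138% to 3.98% with 1 library left out). The 2.12% was the value of Ccl5, whose excess rested on the low first sufficient library. The ratio of these transcripts to Fcer1g within NK cells was not measured here. Scaling left the NK list called by camera at the preset correlation (highest adjusted p = 4.49e-06). In the main fit the list did not pass camera with an estimated correlation (adjusted p = 0.293). For the other NK-list genes NK cells stay open. The median excess of the same 7 transcripts was 35.8% of the excess of Klrd1 (2.89% to 67.8%), and 6.84% over the 5 transcripts other than Gzma and Tyrobp. The 35.8% was the value of Ccl5, at 35.2 and 45.7 FPKM in deficient and 10.3, 51.8 and 42.8 FPKM in sufficient libraries. It rested on the low first sufficient library and cannot decide the question. Macrophages in the sort are a candidate source of the macrophage markers that stays open: 81.3% of the 16 members, 0 of them in another list and 8 at 1 FPKM or more in all sufficient libraries, were higher in the first deficient library and lowest in the first sufficient one, against 18.7% of all genes, with C1qa up to 96.7 and Lyz2 up to 158 FPKM, but this order was read off the same markers and does not test the explanation. Whether myeloid cells also brought the NK-list genes or Fcer1g cannot be told apart from other sources, such as Treg or innate-like T cells: the 7 called NK-list genes had a median ratio of 0.724 between the 2 deficient libraries (Tyrobp 1.68) against quartiles of 1.15 to 2.25 in the macrophage list, but Itgam at 0.551, Ly6c2 at 0.815, Ms4a6c at 1.03 and Fcgr3 at 1.04 of that list lay near the NK genes, and the myeloid excess was 15.7% of that of Fcer1g (8.73% to 23.7%) around a bound of 10%.

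Treg core genes were lower in deficient libraries, while Foxp3 did not pass its test. A larger share of conventional CD4 T cells would lower Foxp3 with the other genes. The log2 fold change of Foxp3 lay 0.77 above the median of the 9 called members, but these were picked as lower in the same data. It lay 0.55 above the median of all 28. Both exceed 2 standard errors of Foxp3 alone, which leave out the spread of the members. Of the conventional CD4 T cell markers 2 of 7, Pde3b and Dapl1, were higher (list median 0.66, camera adjusted p = 0.293 with an estimated correlation). Of these 7 markers 4 are also in another list, among them Dapl1 in that of resting Treg and naive genes. A smaller contribution of conventional CD4 T cells stays open. A lower share of T cells would lower TCR genes alike, but their median of -0.12 lay above the upper quartile of -0.60 of the Treg core list. Scaling did not turn any of the 9 members (highest log2 fold change -0.61). These values are consistent with lower Treg core expression beyond dilution, as a hypothesis, with the mix of Treg subsets in each genotype left untested.

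The 3 near-identical pairs of columns may each be 1 library sequenced in 2 runs, and the pairs also differ in depth. At 500 to 2000 reads, a level not used to merge them, their spread reached 1.79 times sampling noise, against 5.21 to 10.9 in other pairs of the same group. Because that exceeds noise, 1 library sequenced in 2 runs and 2 libraries from 1 RNA cannot be told apart, and no biological explanation was tested.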
